A study of Mus musculus with 12 samples.

How the data were processed

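Pancreatic islets of mice were profiled by RNA sequencing in 12 libraries. Per the labels, stranded mRNA libraries were made from total RNA and sequenced as paired reads of 100 bases. Control mice carry floxed Bmal1, and knockout mice carry in addition a Cre-oestrogen receptor fusion driven by the rat insulin promoter. Per the labels, islets were taken 24 h after citrate buffer (vehicle) or 24 h or 4 wk after a submaximal dose of STZ, with 2 libraries, A and B, in each of 6 groups. The vehicle libraries used here are all labelled 24 h.

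The authors deposited a table of estimated counts (expected counts) per gene, without scaling for depth, and 1 transcript file per library. Per the file headers, transcripts were quantified with StringTie 1.3.6 against a fixed RefSeq annotation of mm10 from UCSC, with the strand option. The aligner is not given in the sources used here. The coverage of each transcript and exon was deposited as the mean depth per base, per the file headers. Every deposited transcript count equals coverage times length over 75, rounded up, although the labels give longer reads, so counts differ from read numbers by a constant factor and both mates are counted. The table holds 24421 genes and 35119 transcripts, of which 4797 genes had 0 counts everywhere, and no mitochondrially encoded gene. Gene coordinates are those of the deposited transcript files, in mm10. Genes whose exons overlap those of another gene by more than 20% were marked with the mouse annotation of GENCODE release M21.

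Total counts of A and B were 111358330 and 104363359 in control vehicle, 109594717 and 121311043 in control STZ 24 h, 111271898 and 127207523 in control STZ 4 wk, 114294922 and 101772241 in knockout vehicle, 112280281 and 120227469 in knockout STZ 24 h, and 106433964 and 126637768 in knockout STZ 4 wk. The 10 most abundant genes took 23.4 to 35.3% of counts. A and B are not copies: their chi-square over degrees of freedom was 25.1 or more, and the gap between them went with GC content, with correlations across genes of -0.71 to 0.63 by group. Genes are not independent replicates in such correlations. Intervals and floors cover counting error only.

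Genes were tested in R 4.3.3 with edgeR 4.0.16: TMM normalisation (factors 0.83 to 1.21), filterByExpr, which kept 17411 genes, and the robust quasi-likelihood F test, a two-sided test. All libraries entered 1 fit of group means (common dispersion 0.0493, 6 residual degrees of freedom, median prior degrees of freedom 2.6). P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. CPM and log2 fold changes were computed here from the counts deposited by the authors, CPM with TMM-scaled library sizes, and SE as the log2 fold change over the root of F. The 12 comparisons are knockout against control in each of the 3 conditions and on their mean, STZ 24 h against vehicle in control and in knockout, STZ 4 wk against vehicle in both, STZ 4 wk against 24 h in both, and the difference of the STZ effect between genotypes (interaction) at 24 h and at 4 wk. Comparisons of 4 wk with vehicle mix treatment and time.

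Of 28 gene lists, 27 had the 5 tested members needed; the list of mitochondrially encoded genes had none. They were tested with camera of limma 3.58.1 on voom values, two-sided, with a preset correlation of 0.01 and adjustment over lists. An estimated correlation was the alternative, and its adjusted p is given where it ends a call. It kept 9 of 17, 12 of 18, 12 of 21, 12 of 19, 3 of 8, 15 of 21, 5 of 15, 14 of 20, 11 of 11, 9 of 18, 14 of 19 and 19 of 20 lists past the threshold in the 12 comparisons in the order above.

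Exon coverage of Arntl was computed from the coverage the authors deposited, as log2 of exon over transcript mean with a pseudocount of 0.1. It was tested between 6 knockout and 6 control libraries by an exact two-sided permutation test over the 20 annotated exons, with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

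Comparisons, tests, gene lists, other settings to try and the rule for named genes were fixed before the data were examined. The rule names Arntl, the 10 largest gains and losses past the threshold with a mean CPM of at least 2 (5 of each in the comparisons of 4 wk with 24 h and in the interactions), the 4 members of smallest adjusted p of each described list, and 10 fixed genes. The results of some genes that the rule names are not reported here. Which lists are described was chosen after the results were seen. Settings fixed in this way were DESeq2 1.42.0 size factors, no filter (19624 genes), the DESeq2 Wald test, the replicate letter as a block, the acinar score (mean log2 CPM of the acinar list) as a covariate, leaving out each library, and a fit of only the 4 libraries compared. The gap between A and B correlated across genes between the genotypes of a condition, at 0.4 under vehicle, 0.18 at 24 h and 0.82 at 4 wk after STZ. The labels name no shared litter, batch or day, so this is only a hint that letters pair the genotypes. A fit with that pairing within conditions, chosen after seeing the data, leaves 3 residual degrees of freedom, and is given where it changes a call. A group left with 1 library is assumed to vary like the other groups.

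Chosen after seeing the data were total-count scaling, scaling to 20 pan-endocrine genes, an offset for GC content (known for 96% of tested genes), counts rescaled to fragments, and 9 lists of genes selective for liver, intestine, stomach, lymphoid tissue, kidney, fat, beta cells, alpha cells or all endocrine cells.

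The edgeR step was tested on 5 simulated draws of knockout against control under vehicle, with 200 of 17411 genes changed. It recovered 1.2% of genes changed 1.5-fold, 23.3% changed 2-fold and 66.1% changed 4-fold, with 17 false calls of 317. The list test called only the list that had been moved, of 27.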

Results

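Islets from mice with floxed Bmal1 (control) were compared with islets from mice in which tamoxifen-inducible Cre deletes Bmal1 in beta cells (knockout). Mice received vehicle or streptozotocin (STZ), a toxin taken up by beta cells. The comparisons ask how islet transcription responds to this injury and whether the response differs without BMAL1. Under vehicle, the clock genes Npas2, Cry1 and Nfil3 were higher in knockout and most E-box targets of CLOCK:BMAL1 were lower. After STZ, knockout libraries held more macrophage and interferon and fewer beta-cell transcripts than control libraries at 24 h and 4 weeks (4 wk). Scaled to pan-endocrine genes, which beta-cell loss would lower too, beta-list medians were -0.27 and -0.22 (log2). Transcripts of acinar cells, liver, intestine, stomach and lymphoid tissue moved between groups too.

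The 12 libraries form the 6 groups of 2 replicates, A and B, named above. The labels do not say that A and B come from separate animals, so p-values measure only the spread between these libraries, which may be technical. If A and B were prepared together, that preparation's tissue content and hour cannot be told from STZ or genotype effects. Levels are in CPM, as mean ± SD of 2 libraries. Log2 is short for log2 fold change. Members of a gene list counted as higher or lower passed an adjusted p of 0.05 over all genes, and in brackets are the numbers up and down when adjusted over the list alone, followed by the median log2 of the list and its own test. Another scaling shifts all log2 values of a comparison by nearly the same amount, about the median gene given for it. "Endocrine" or "total-count" before a value gives it under pan-endocrine or total-count scaling, where a call or list median turns sign or the median moves by over 1.5 times, with an adjusted p where a list call ends. Calls that ended "without A or B" did so with some single library left out. "Letters paired" marks a fit that pairs A with A and B with B between genotypes within a condition. A fold against a group with 0 counts is given as a lower bound, set at 3 counts over the group.

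Arntl, the gene for BMAL1, is the target of the knockout (chromosome 7, 113207465 to 113314126, mm10). Its exon 8, a coding exon from 113284999 to 113285156, had a coverage relative to the transcript mean of 1.71 ± 0.16 in control and 0.88 ± 0.29 in knockout (SD, n = 6 each). The log2 difference of -1.02 had an exact two-sided permutation p of 0.00216, adjusted over 20 exons to 0.0433. All 6 knockout libraries lay below all 6 control libraries, so the exon goes with every genotype label, although the labels do not name the floxed exon. Scaled to library totals instead, exon 8 differed by -0.95 with an exact permutation p of 0.0108, and the adjusted p of 0.216 did not pass. The whole transcript was higher in knockout under vehicle, 18.9 ± 1.46 against 8.58 ± 0.301 CPM (log2 1.14, SE 0.11, adjusted p = 0.000238). It did not pass at 24 h after STZ (log2 -0.26 (endocrine 1.46), SE 0.11, adjusted p = 0.0877) and was lower at 4 wk (log2 -0.84, SE 0.11, adjusted p = 0.000548), and its mean over the 3 conditions did not pass (log2 0.01, SE 0.06, adjusted p = 0.948).

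**Figure D1:**
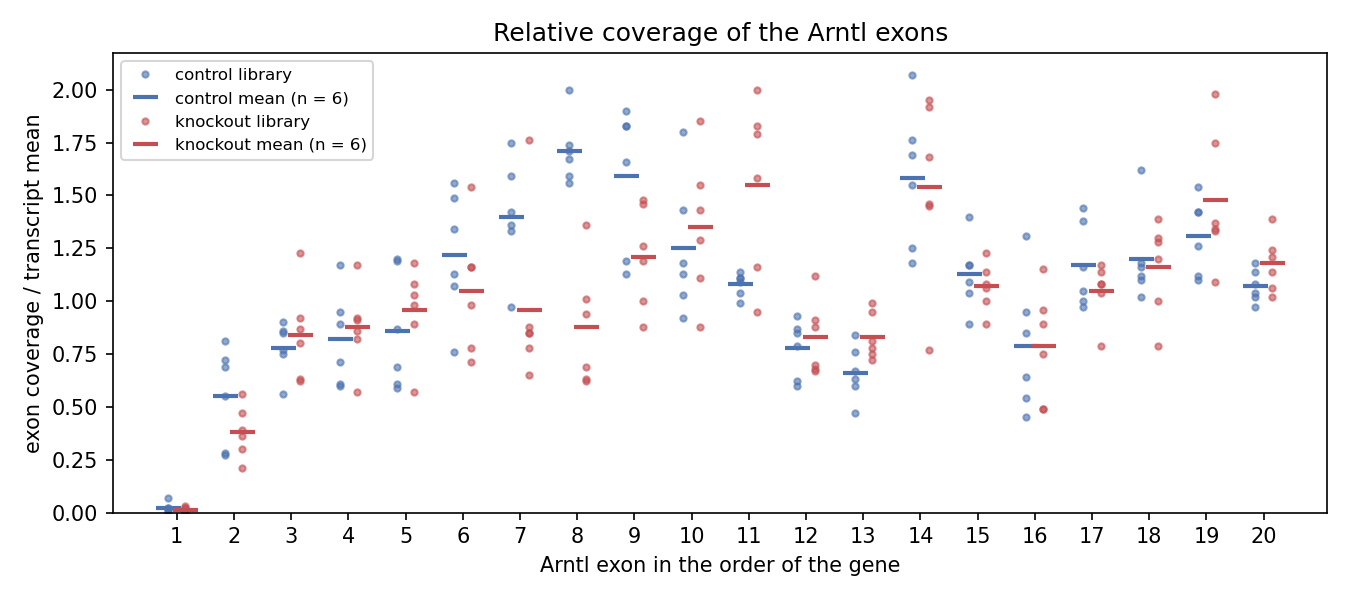
Coverage of each Arntl exon relative to the transcript mean, with 1 point per library and means by genotype. Exon 8 lies lower in all 6 knockout libraries than in the 6 control libraries.

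**Figure D2:**
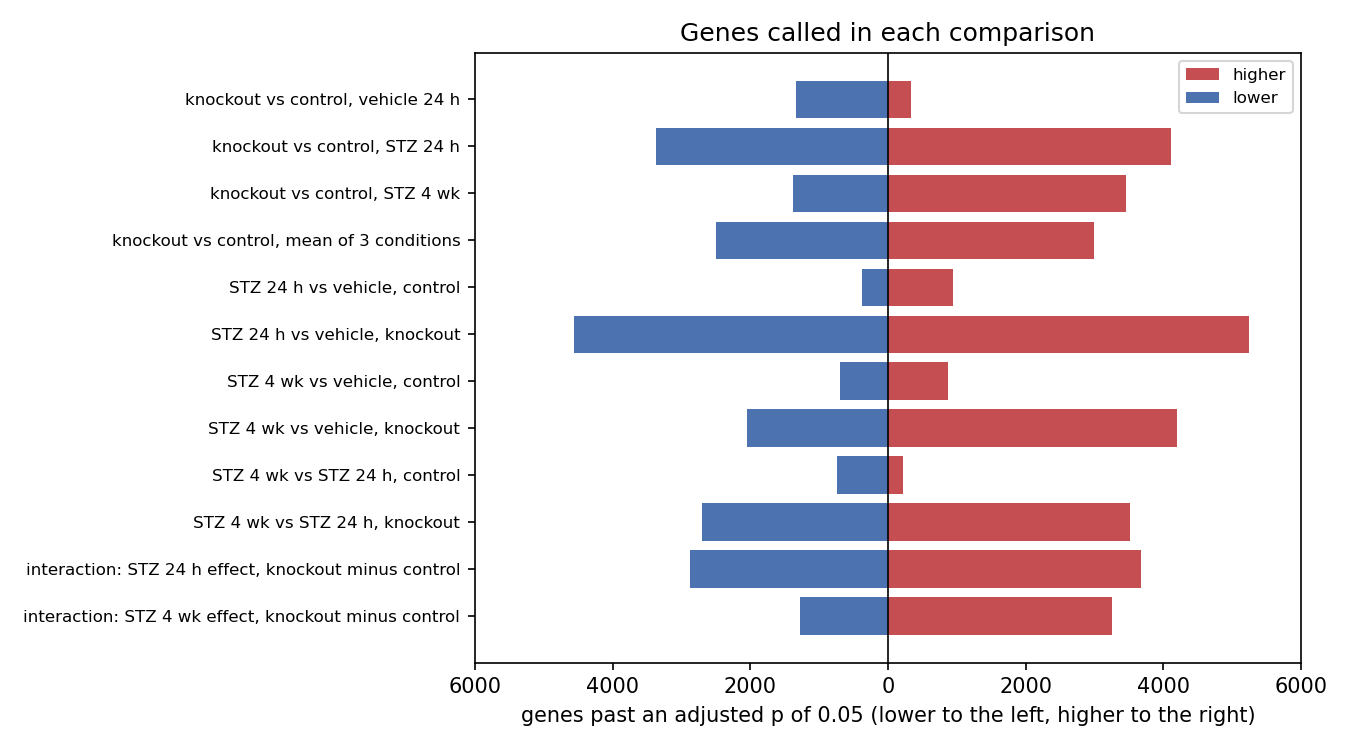
Genes higher and lower past an adjusted p of 0.05 in each comparison. Totals run from 956 in control islets between 24 h and 4 wk to 9814 in knockout islets 24 h after STZ, and the split changes under the scalings given with each comparison.

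The vehicle comparison asks what Bmal1 loss does in uninjured islets. Core clock genes and cholesterol synthesis genes were higher in knockout, and E-box outputs, immediate early genes and NF-kB targets were lower. Acinar transcripts were several fold lower, and 9 of 13 stomach genes were lower, some with 0 counts in knockout. In all, 1679 of 17411 genes passed (3533 with letters paired, 3128 with an offset for GC content), 342 higher and 1337 lower. Under total-count scaling 6221 were higher and 984 lower (median gene 0.53), and under pan-endocrine scaling 102 and 3321 (median -0.37). Without A or B of either group, between 1070 and 1228 passed.

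Of 11 core clock genes other than the E-box outputs below, 5, Arntl among them, rose and 0 fell (5 up, 0 down alone), median log2 0.68 (total-count 1.21, endocrine 0.30), adjusted p = 3.65e-08. Npas2, which can stand in for CLOCK, went from 1.73 ± 0.275 to 19.5 ± 0.373 CPM (log2 3.50, SE 0.22, adjusted p = 1.86e-05; chromosome 1, 39194272 to 39363240). The repressor gene Cry1 rose by 2.54, with Nfil3 at 1.82 (adjusted p up to 6.51e-05). Among 14 E-box outputs, 8 fell and 1, Per2, rose (1 up, 9 down alone), median log2 -0.64 (total-count -0.11, endocrine -1.03), adjusted p = 7.35e-05. Per2 reached 47.9 ± 3.24 against 22.5 ± 1.17 CPM (log2 1.09, SE 0.12, adjusted p = 0.00051). The REV-ERB genes Nr1d1 and Nr1d2, the repressor genes Ciart and Cry2, and the output gene Dbp fell (log2 -2.31 to -0.88, adjusted p up to 0.00815).

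Cholesterol and lipid synthesis genes rose in 10 of 24 and fell in 0 (14 up, 0 down alone), median log2 0.59 (total-count 1.12, endocrine 0.20), adjusted p = 4.01e-11. They include Hmgcs1 and Sqle of sterol synthesis and the desaturase gene Scd2 (log2 0.64 to 0.98, adjusted p up to 0.00387). Of 22 immediate early genes, which tissue dissociation raises, 11 fell and 1 rose (1 up, 13 down alone), median log2 -1.02 (total-count -0.49), adjusted p = 3.1e-07; Fosb, Fos, Egr1 and Zfp36 led (log2 -2.79 to -1.31, adjusted p up to 8.12e-05). NF-kB targets fell in 11 of 33 and rose in 0 (0 up, 12 down alone), adjusted p = 1.73e-06. In the beta-identity list 1 of 25 genes, Nkx2-2 (0.60, adjusted p = 0.0302), rose and 0 fell (4 up, 0 down alone), median log2 0.33 (total-count 0.86, endocrine -0.06), adjusted p = 0.000239. Ins1, Ins2, Mafa, the glucose transporter gene Slc2a2, Gcg and the cell-cycle inhibitor gene Cdkn1a did not pass (log2 -0.33 to 1.36, adjusted p at least 0.626; total-count 0.44 for Cdkn1a), although pairing the letters gave adjusted p = 0.0462 for Ins1.

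Among genes with a symbol other than a model name and a mean of at least 2 CPM in the libraries compared, the limit for all largest gains and losses here, Esr1 had the largest gain, 341 ± 25.1 against 0.905 ± 0.0892 CPM (log2 8.55, SE 0.25, adjusted p = 3.73e-07; chromosome 10, 4611989 to 5005633). Next came the glycogen-targeting gene Ppp1r3c, the potassium channel gene Kcnk13, the magnesium transporter gene Slc41a3, Tcf24, Relt and the heat-shock gene Hspa1a (log2 1.87 to 3.54, adjusted p up to 0.03). The largest losses had 0 counts in knockout: Gkn2, Gkn1, Tff1 and Muc5ac of the stomach lining (at least 980-fold each), and Clca1, Lypd8, Sprr2a2, Gsta1, Mug1 and Cnn1 of other linings, liver and smooth muscle (at least 437-fold each). Sprr2a2 shares sequence with Sprr2a1. Stomach genes took 0.0227% of control counts and 0.000876% of knockout counts, liver genes 0.0196% and 0.00476%, and lymphoid-tissue genes 0.00288% and 0.000128%. Of 30 acinar genes, 28 fell and 0 rose (0 up, 30 down alone), median log2 -2.15, adjusted p = 5.98e-45; Pnlip, Zg16, Rnase1 and Prss2 are examples (log2 -2.20 to -2.13, adjusted p up to 3.89e-06). Their share was 38% ± 0.636 in control and 12.5% ± 0.141 in knockout. Calls of Hspa1a, Nkx2-2, Dbp and Nr1d1 ended without A or B of either group (adjusted p 0.0509 to 0.203).

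**Figure D3:**
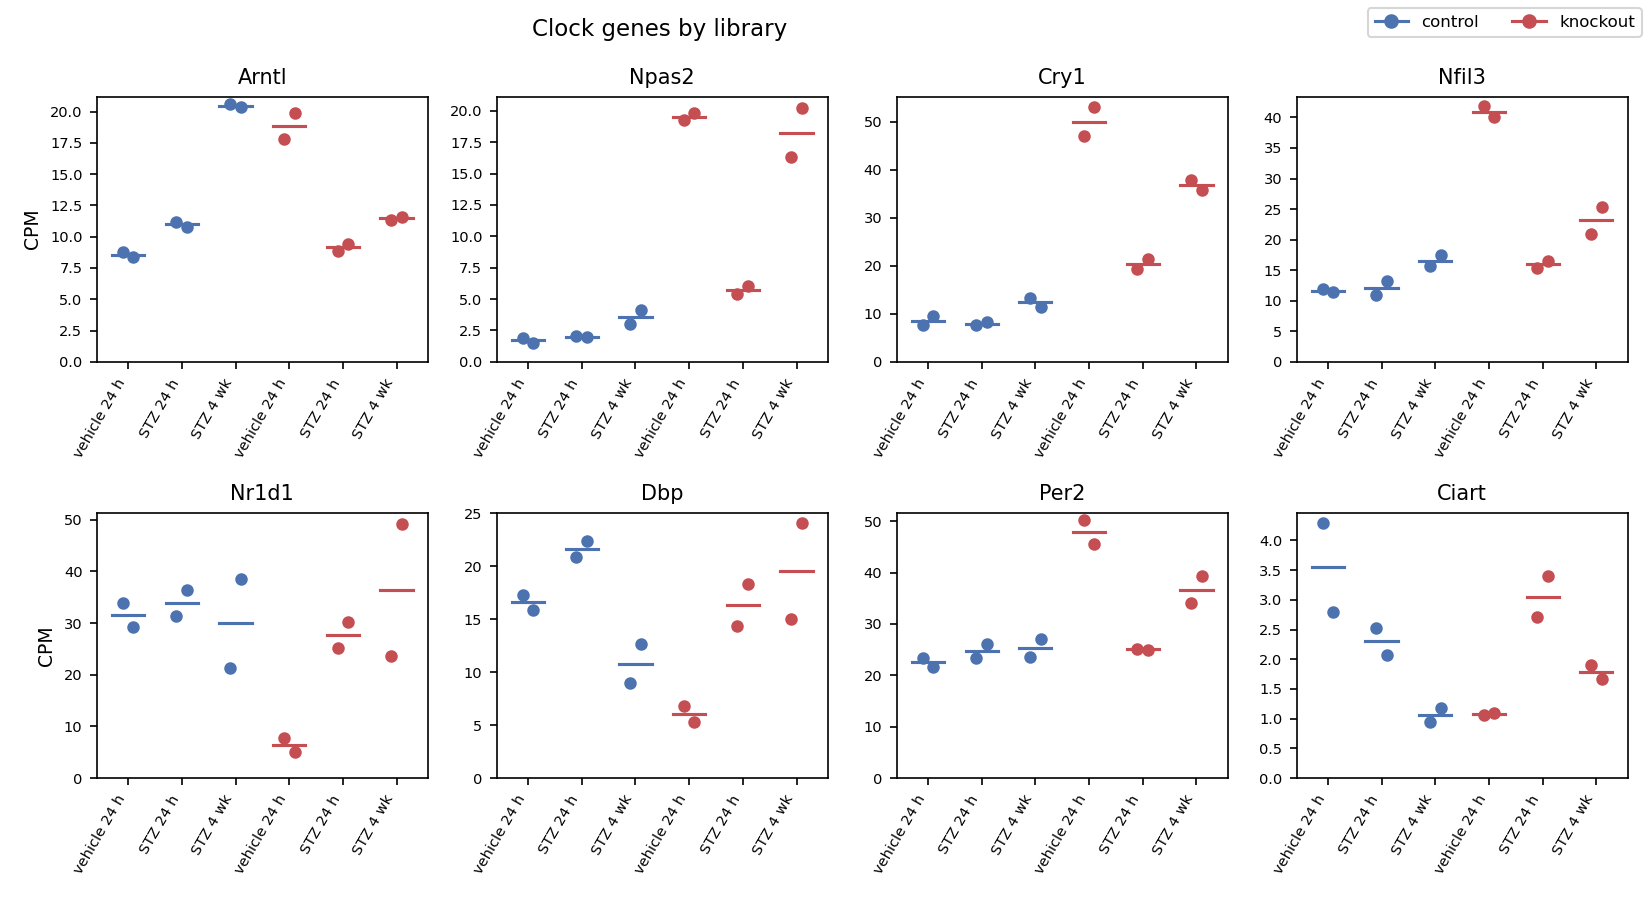
CPM of clock genes in each library, with group means. Npas2, Cry1 and Nfil3 lie higher in knockout than in control in each condition, and Dbp lies lower in knockout under vehicle and higher at 4 wk.

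The comparison at 24 h after STZ asks whether acutely injured islets differ by genotype. Macrophage and interferon genes were higher in knockout in nearly every member, as were most NF-kB targets, and beta-identity and secretion genes were lower. The p53 target Cdkn1a was higher, and liver, lymphoid and acinar transcripts were higher with the macrophage genes. In all, 7491 genes passed, 4119 higher and 3372 lower. Under total-count scaling 3318 were higher and 5183 lower (median gene -0.24), and under pan-endocrine scaling 14439 and 115 (median 1.72).

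All 28 macrophage genes rose (28 up, 0 down alone), median log2 2.96 (endocrine 4.68), adjusted p = 7e-16. The lysozyme gene Lyz2 went from 59.98 ± 2.21 in control to 653 ± 23.2 CPM in knockout (log2 3.45, SE 0.12, adjusted p = 5.93e-07; chromosome 10, 117277541 to 117282272). H2-Aa of antigen presentation, the cathepsin gene Ctss and Lgals3 rose with it (log2 2.70 to 3.45, adjusted p up to 2.67e-06). Interferon genes rose in 34 of 36 and fell in 0 (34 up, 0 down alone), median log2 1.73 (endocrine 3.46), adjusted p = 1.77e-12. The factor gene Irf8, Gbp3 and the antiviral gene Bst2 were among them (log2 2.39 to 4.71, adjusted p up to 1.05e-05). NF-kB targets rose in 23 of 33 (adjusted p = 3.07e-10), lymphocyte and neutrophil genes in 19 of 19 (adjusted p = 3.56e-10), and MHC class I genes in 13 of 19 (adjusted p = 4.69e-05, and adjusted p = 0.173 with an estimated correlation). Targets of p53 rose in 19 and fell in 2 of 34 (adjusted p = 0.000258), with Cdkn1a at 158 ± 4.45 against 23.3 ± 0.574 CPM (log2 2.76, SE 0.10, adjusted p = 8.32e-07). Beside these, lymphoid-tissue genes took 0.0741% of knockout and 0.000496% of control counts, liver genes 1.92% ± 0.0354 and 0.658% ± 0.00354, and intestinal genes 0.0898% and 0.0122%.

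Of 25 beta-identity genes, 22 fell and 0 rose (0 up, 24 down alone), median log2 -1.99 (endocrine -0.27), adjusted p = 7.97e-14. The channel gene Trpm5, the incretin receptor gene Glp1r, the zinc transporter gene Slc30a8 and Iapp fell most clearly (log2 -3.02 to -2.22, adjusted p up to 2.7e-06). Ins1 went from 34690 ± 2252 in control to 5411 ± 405 CPM in knockout (log2 -2.68, SE 0.34, adjusted p = 0.000291), and Ins2 and Slc2a2 fell (log2 -2.36 to -2.27, adjusted p up to 0.00243), while Mafa was at -2.99, adjusted p = 0.0718, and adjusted p = 0.000958 for Mafa with letters paired. Secretion-coupling and exocytosis genes fell in 22 of 25 and rose in 0 (0 up, 22 down alone), median log2 -1.67 (endocrine 0.05), adjusted p = 2.77e-12. They include the calcium channel genes Cacna1d and Cacna1c, Ptprn2 and the granin gene Chgb (log2 -1.75 to -1.58, adjusted p up to 6.55e-06; endocrine 0.05 to 0.14 for Cacna1d and Chgb). Alpha-cell genes fell in 7 and rose in 1 of 15, with median log2 -0.95 (endocrine 0.77), adjusted p = 0.00253, and Gcg was at -1.46 (endocrine 0.27), adjusted p = 6.3e-06. Acinar genes rose in 21 of 30 (28 up, 0 down alone), median log2 1.08 (endocrine 2.80), adjusted p = 2.52e-09; Prss2 was at 1.09, adjusted p = 4.59e-05.

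Ductal genes rose in 12 and fell in 1 of 18 (median log2 1.16 (endocrine 2.89), adjusted p = 0.00164, and adjusted p = 0.13 with an estimated correlation), and genes disallowed in mature beta cells in 15 and 5 of 23 (adjusted p = 0.00118, and adjusted p = 0.13 with an estimated correlation). Senescence genes rose in 15 of 25 (adjusted p = 3.79e-05) and endothelial genes in 8 of 17 (median log2 0.66 (total-count 0.41, endocrine 2.38), adjusted p = 0.0402, and adjusted p = 0.173 with an estimated correlation). Delta- and PP-cell, DNA repair, glycolysis, oxidative phosphorylation and Schwann-cell lists did not pass (adjusted p = 0.788, 0.523, 0.523, 0.188 and 0.523). Dbp, Nr1d1 and Per2 did not pass (log2 -0.40 to 0.02, adjusted p at least 0.243; endocrine 1.32 to 1.43 for Dbp and Nr1d1), although pairing the letters gave adjusted p = 0.0104 for Dbp and 0.0424 for Nr1d1. The genes with the largest gains had 0 counts in control (at least 439-fold each). They mark lymph node (Glycam1, Cxcr5, Cd3d, H2-Eb2) and gut (Tmprss15, Clca4a, Adh6a, Ptprh), besides Psg22 and the protease gene Mmp10. The largest losses were the neuronal genes Cntnap2, Csmd2, Fam19a1 and Kcnf1, the opioid precursor gene Pdyn, Cox6a2, Car10 and T2 (log2 -4.28 to -3.04, adjusted p up to 0.000101). Amd1, which shares sequence with Amd2, had a control to knockout ratio of 964 (95% interval 267 to 7960), and Pcdhac1, which overlaps Pcdhac2, was at -4.86, adjusted p = 0.0324. Both rest on single libraries: without A or B of either group the calls of Amd1 and Pcdhac1 ended (adjusted p 0.0954 to 0.988).

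The comparison at 4 wk after STZ asks whether the difference lasts. Macrophage and interferon genes were still higher and beta-cell genes still lower in knockout. Of the E-box outputs 7 of 14 were higher, opposite to vehicle, but the call of the list ended with an estimated correlation (adjusted p = 0.106) and without control STZ 4 wk A or knockout STZ 4 wk B. In all, 4839 genes passed (8184 with letters paired, 7568 with the GC offset), 3465 higher and 1374 lower. Under total-count scaling 3194 were higher and 2037 lower, and under pan-endocrine scaling 9024 and 84 (median gene 0.72).

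Macrophage genes rose in 26 of 28 and fell in 0 (26 up, 0 down alone), median log2 1.77, adjusted p = 2.18e-12. Lgals3, a galectin gene, went from 2.87 ± 0.444 to 117 ± 2.9 CPM (log2 5.35, SE 0.19, adjusted p = 5.75e-07), and Lyz2, H2-Aa and Ctss rose (log2 1.74 to 1.90, adjusted p up to 7.4e-06). Interferon genes rose in 28 of 36 and fell in 0 (30 up, 1 down alone), median log2 1.11 (endocrine 1.82), adjusted p = 3.86e-09; Irf7, Ifit1, Oasl2 and Gbp3 are examples (log2 1.81 to 3.25, adjusted p up to 6.81e-05). Intestinal genes took 1.38% ± 0.0212 of knockout counts beside them and 0.0388% ± 0.000354 of control counts, liver genes 0.539% and 0.204%, and acinar genes 25.1% and 20.8%.

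Of 25 beta-identity genes, 20 fell (0 up, 21 down alone), median log2 -0.92 (endocrine -0.22), adjusted p = 2.42e-12. Glp1r, Trpm5, Slc30a8 and the maturity marker Ucn3 fell most clearly (log2 -1.89 to -1.12, adjusted p up to 9.46e-05). Slc2a2 was at -0.56 (endocrine 0.16), adjusted p = 0.00822 and Ins1 at -1.16, adjusted p = 0.0274, while Ins2 (-0.92, adjusted p = 0.135) and Mafa (-1.90, adjusted p = 0.248) did not pass. With letters paired both passed (adjusted p = 0.000374 for Ins2 and 0.0041 for Mafa). Without the pairing these genes depend on single libraries, with Ins1 at adjusted p = 0.144 without control STZ 4 wk B and 0.0983 without knockout STZ 4 wk A, Ins2 and Mafa at 0.0213 and 0.0396 without knockout STZ 4 wk B. Secretion genes fell in 15 of 25 (0 up, 17 down alone), median log2 -0.63 (endocrine 0.07), adjusted p = 2.34e-08; Cacna1c, Chgb, Cacna1d and Rapgef4 are examples (log2 -0.69 to -0.52, adjusted p up to 0.0023; endocrine 0.03 to 0.19 for all). Unfolded-protein genes fell in 12 and rose in 3 of 29, with median log2 -0.53 (endocrine 0.19), adjusted p = 7.29e-05. Cdkn1a was higher (1.59, adjusted p = 6.97e-06) and Gcg did not pass (0.08, adjusted p = 0.597).

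Of 14 E-box outputs, 7 rose and 1 fell (8 up, 1 down alone), median log2 0.55 (endocrine 1.26), adjusted p = 0.0388, and adjusted p = 0.106 with an estimated correlation; the list had adjusted p = 0.0784 without control STZ 4 wk A and 0.139 without knockout STZ 4 wk B, and 0.0678 with the GC offset. Bhlhe40, Hlf, Usp2, Tef, Dbp and Per2 rose (log2 0.53 to 2.25, adjusted p up to 0.0374), and Nr1d1 was at 0.28, adjusted p = 0.652. The largest gains were intestinal and had 0 counts in control: the Paneth-cell defensin genes Defa23, Defa17 and Defa3, which share sequence, with Itln1, Enpp7, Clca3b, Cyp2b9 and Mptx2 (at least 488-fold each). Defa24 had a ratio of 11900 (95% interval 2130 to 469000), and Slc5a12 was at 12.67, adjusted p = 1.38e-05. Acinar genes rose in 11 of 30 (12 up, 0 down alone), median log2 0.36 (endocrine 1.07), adjusted p = 0.00374, and adjusted p = 0.0568 with an estimated correlation; Prss2 was at 0.39, adjusted p = 0.0193. The largest losses were Atp6v0c, which shares sequence with a pseudogene, Angptl7, the liver genes Hsd3b5, Elovl3 and Mup15, Aak1, Cyp4f39, Cox6a2, Car10 and Adam32 (log2 -6.52 to -1.92, adjusted p up to 0.0275). Calls of Aak1, Mup15, Ins1, Slc2a2, Dbp, Per2 and Prss2 ended without A or B of either group (adjusted p 0.0509 to 0.196), and that of Aak1 with letters paired (adjusted p = 0.132 for Aak1).

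Averaged over the 3 conditions, macrophage and interferon genes were higher and beta-cell genes lower in knockout. The average covers opposite effects: of the genes lower in knockout under vehicle, 1053 were higher at 24 h after STZ, against 316 by chance. In all, 5491 genes passed (8619 with letters paired), 2994 higher and 2497 lower, with 12307 higher and 210 lower under pan-endocrine scaling (median gene 0.67). Macrophage genes rose in 26 of 28 (26 up, 0 down alone), median log2 1.45, adjusted p = 7.26e-17; Lgals3, Lyz2, H2-Aa and Ctss led (log2 1.34 to 2.52, adjusted p up to 2.26e-06). Interferon genes rose in 34 of 36 (34 up, 0 down alone), median log2 0.95 (endocrine 1.64), adjusted p = 7.48e-16, among them Gbp3, Gbp2 and Oasl2 (log2 1.14 to 1.39, adjusted p up to 2.13e-05). Beside these, intestinal genes rose in 12 of 20 (adjusted p = 8.35e-10) and lymphoid-tissue genes in 10 of 20 (adjusted p = 1.1e-07), and acinar genes fell in 9 and rose in 1 of 30, with median log2 -0.23 (endocrine 0.46), adjusted p = 0.000594. Core clock genes rose in 4 of 11 (4 up, 0 down alone), median log2 0.17 (endocrine 0.85), adjusted p = 0.0101, and adjusted p = 0.0597 with an estimated correlation; Npas2, Cry1 and Nfil3 are among them (log2 0.90 to 2.45, adjusted p up to 5.45e-05). Beta-identity genes fell in 22 of 25 (0 up, 22 down alone), median log2 -0.82 (endocrine -0.13), adjusted p = 2.29e-14. Trpm5, Glp1r, Slc30a8, Ucn3, Slc2a2, Ins1 and Ins2 are among them (log2 -1.65 to -0.91, adjusted p up to 0.0169). Secretion genes fell in 21 of 25 (0 up, 21 down alone), median log2 -0.69 (endocrine -0.01), adjusted p = 1.39e-11, led by Cacna1c, Chgb, Cacna1d and Pclo (log2 -0.99 to -0.62, adjusted p up to 4.49e-05; endocrine 0.07 for Cacna1d).

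The largest mean gains were Ifi202b, an interferon-inducible gene, Glod5 and Esr1, which was at 6.83, adjusted p = 9.71e-08, and the intestinal genes Guca2b, Slc15a1, Defa24, Dnase1, Mogat2, Naaladl1 and Muc2 (adjusted p up to 0.0108). The largest mean losses were liver genes: Saa1, Saa2, Mug1, Mug2, Ces1c, Sult2a8, Hsd3b5 and the urinary protein genes Mup14, Mup15 and Mup16, which share sequence (adjusted p up to 0.0485). All of these except Esr1 had 0 counts in at least 1 group, so their mean log2 depends on the prior count and is not given; the liver genes among them had 0 counts in knockout vehicle, whereas the liver list was higher in knockout after STZ. Cdkn1a and Per2 were higher (log2 0.55 to 1.42, adjusted p up to 0.000409). Gcg, Nr1d1 and Prss2 were lower (log2 -0.77 to -0.22, adjusted p up to 0.0273; endocrine 0.24 to 0.46 for Gcg and Prss2), and Dbp and Mafa did not pass (log2 -1.17 to -0.33, adjusted p at least 0.13; endocrine 0.35 for Dbp). Calls of Guca2b, Slc15a1, Defa24, Dnase1, Naaladl1, Muc2, Mup16, Hsd3b5, Ins2, Nr1d1 and Prss2 ended without A or B of any group except control STZ 4 wk A (adjusted p 0.0514 to 1), and Mafa and Dbp passed without knockout STZ 4 wk B (adjusted p 0.0301 and 0.0246). With letters paired Mafa and Dbp passed and Mup16 did not (adjusted p = 0.00319 for Mafa, 0.00202 for Dbp and 0.0834 for Mup16).

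In control islets at 24 h after STZ, acinar genes fell and macrophage and cell-cycle genes rose, while no beta-identity gene passed. Liver transcripts rose and stomach transcripts fell. In all, 1317 genes passed (2515 with the GC offset), 942 higher and 375 lower, with 2408 higher and 226 lower under total-count scaling (median gene 0.33) and a median of -0.11 under pan-endocrine scaling. Without A or B of either group, between 770 and 854 passed. Of 30 acinar genes, 19 fell (0 up, 23 down alone), median log2 -0.87 (total-count -0.56), adjusted p = 6.34e-23; Reg2 and Reg1 of regeneration, Prss2 and Pnliprp2 led (log2 -2.25 to -0.99, adjusted p up to 0.000229). Proliferation genes rose in 8 of 32 (14 up, 0 down alone), median log2 0.60 (total-count 0.91), adjusted p = 7.14e-08, among them the replication gene Mcm3 and the mitotic genes Cenpf, Cenpe and Cdk1 (log2 0.92 to 1.24, adjusted p up to 0.0221). Macrophage genes rose in 10 of 28 (14 up, 0 down alone), median log2 0.67, adjusted p = 7.34e-08; Lyz2 went from 20.9 ± 0.382 to 59.98 ± 2.21 CPM (log2 1.52, SE 0.11, adjusted p = 2.91e-05), and the scavenger receptor genes Mrc1 and Cd163 and Gpnmb rose (log2 2.18 to 2.93, adjusted p up to 0.00284). Stellate-cell and fibroblast genes rose in 11 and fell in 1 of 24 (15 up, 2 down alone), median log2 0.93, adjusted p = 9.47e-06, and adjusted p = 0.148 with an estimated correlation. Examples are Fn1, which liver also makes, Bgn, Pdgfra and Col3a1 (log2 1.02 to 2.72, adjusted p up to 0.00104).

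Ins1, Ins2, Mafa, Slc2a2, Arntl, Dbp, Nr1d1 and Per2 did not pass (log2 0.11 to 1.69, adjusted p at least 0.108), and Gcg and Cdkn1a were lower (log2 -0.90 to -0.63, adjusted p up to 0.00218). Liver genes went from 0.0196% to 0.658% of counts. Cyp4a12a, Mup21, Acsm5 and Agmat of liver, and Ccl21b of lymphatic vessels, had 0 counts under vehicle (at least 256-fold each). Mup20, Cyp2a5 and Cyp2d9 rose (log2 8.45 to 9.84, adjusted p up to 0.000351), and the ratios of Hsd3b5 and the clotting gene F11 were 696 (95% interval 238 to 3380) and 318 (95% interval 109 to 1550). The stomach genes Gkn2, Gkn1, Muc5ac, Psca and Cldn18 fell to 0 counts (at least 333-fold each), and Dpcr1, Anxa10, Tff1 and the B-cell genes Cr2 and Ms4a1 fell (log2 -6.89 to -4.77, adjusted p up to 0.00125). Calls of Psca, Cldn18, Cenpf, Cenpe and Cdk1 ended without A or B of either group (adjusted p 0.0523 to 0.151).

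In knockout islets at 24 h after STZ, macrophage, interferon and acinar genes rose in nearly every member. Beta-cell genes fell, and liver, intestinal and lymphoid transcripts rose from near 0. In all, 9814 genes passed, 5247 higher and 4567 lower. Under total-count scaling 4085 were higher and 7563 lower (median gene -0.47), and under pan-endocrine scaling 14701 and 91 (median 1.96). All 28 macrophage genes rose (28 up, 0 down alone), median log2 3.98, adjusted p = 4.95e-14; Lyz2 went from 11.1 ± 0.0155 to 653 ± 23.2 CPM (log2 5.88, SE 0.13, adjusted p = 1.04e-08), with Ctss, Lgals3 and H2-Aa (log2 3.49 to 5.60, adjusted p up to 8.98e-08). Interferon genes rose in 34 and fell in 1 of 36 (34 up, 1 down alone), median log2 1.91 (endocrine 3.87), adjusted p = 2.33e-10, among them Gbp3, Bst2 and Gbp2 (log2 3.02 to 3.52, adjusted p up to 1.05e-06). All 30 acinar genes rose (30 up, 0 down alone), median log2 2.43 (endocrine 4.40), adjusted p = 5.64e-13. They went from 12.5% to 41.6% of counts, with Try5, Rnase1, Zg16 and Prss2 as examples (log2 2.17 to 3.06, adjusted p up to 4.42e-07). Liver genes went from 0.00476% to 1.92% of counts: Mug1, Ces1c, Apoh, Bhmt, Orm1, Hrg and Ces3a had 0 counts under vehicle, as did Marco of marginal-zone macrophages and Clca1 and Akp3 of gut (at least 17500-fold each).

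Of 25 beta-identity genes, 22 fell (0 up, 23 down alone), median log2 -2.08 (endocrine -0.12), adjusted p = 1.31e-11. Their share of counts went from 13.6% ± 3.54 to 2.2% ± 0.163. Trpm5, Slc30a8, Iapp, Glp1r, Slc2a2, Ins2, Ins1 and the alpha-cell hormone gene Gcg fell (log2 -2.82 to -1.85, adjusted p up to 0.00216; endocrine 0.12 for Ins1), and Mafa was at -2.66, adjusted p = 0.0824. Core clock genes fell in 6 and rose in 1 of 11 (1 up, 7 down alone), median log2 -1.04 (endocrine 0.92, adjusted p = 0.456), adjusted p = 0.00368. Nfil3, Cry1, Arntl and Per2 were lower (log2 -1.36 to -0.94, adjusted p up to 0.000185; endocrine 0.60 to 1.03 for all), and Dbp and Nr1d1 were higher (log2 1.43 to 2.13, adjusted p up to 0.00177). Cdkn1a rose by 1.96, adjusted p = 5.98e-07. The largest losses were Cntnap2, Adam32, Fam19a1, Csmd2, Ptprt, Spock1, Nell1, Car10, Cox6a2 and Pcdha12, which overlaps Pcdhac2 (log2 -4.52 to -3.01, adjusted p up to 0.00653). The call of Pcdha12 ended with adjusted p = 0.055 without knockout STZ 24 h B.

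**Figure D4:**
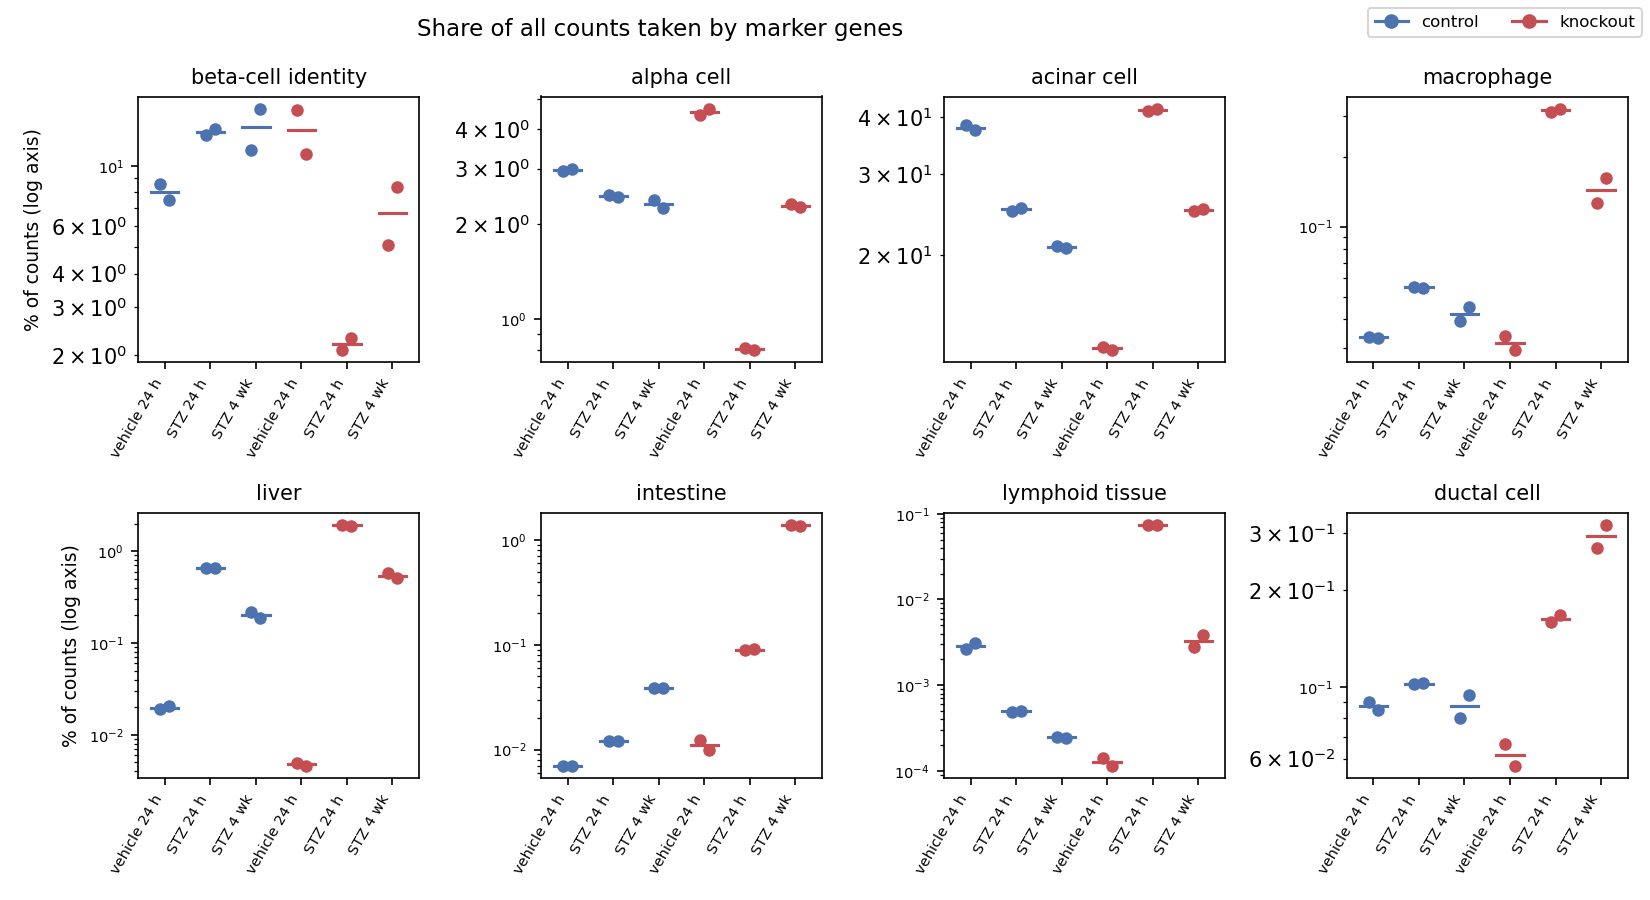
Percent of counts on marker genes of islet, acinar, immune and other-tissue cells in each library, on a logarithmic axis. Liver and lymphoid shares lie highest in knockout at 24 h after STZ, and intestinal shares in knockout at 4 wk.

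Control islets at 4 wk after STZ were compared with vehicle islets at 24 h, so treatment and time change together, because no vehicle group at 4 wk was analysed here. Acinar, immediate early, inflammatory and E-box genes were lower, and Arntl and some beta-identity genes were higher. In all, 1565 genes passed (2842 with the GC offset), 867 higher and 698 lower. Under total-count scaling 3852 were higher and 455 lower (median gene 0.41), and under pan-endocrine scaling 596 and 1441 (median -0.26). Without A or B of either group, between 941 and 1131 passed. Of 30 acinar genes, 24 fell (0 up, 24 down alone), median log2 -1.20, adjusted p = 1.28e-32; Reg2, Prss3, Pnliprp2 and Prss2 are examples (log2 -4.26 to -1.37, adjusted p up to 4.89e-05). Immediate early genes fell in 9 of 22 (1 up, 13 down alone), median log2 -0.66 (total-count -0.28), adjusted p = 3.73e-09, led by Zfp36, Fosb, Jun and Hspa1b (log2 -2.21 to -1.04, adjusted p up to 0.00263). NF-kB targets fell in 9 and rose in 1 of 33 (1 up, 11 down alone), adjusted p = 0.000129, with Lcn2, Saa3, Nfkbia and Ccl3 among the lower ones (log2 -6.19 to -0.60, adjusted p up to 0.0101). E-box outputs fell in 6 of 14 (0 up, 6 down alone), median log2 -0.60 (total-count -0.22, endocrine -0.91), adjusted p = 5.28e-06, led by Cry2, Bhlhe40, Ciart and Usp2 (log2 -1.74 to -0.67, adjusted p up to 0.0238). Core clock genes rose in 3 of 11 (5 up, 0 down alone), median log2 0.49 (total-count 0.87, endocrine 0.18), adjusted p = 0.00406, and adjusted p = 0.0576 with an estimated correlation; Arntl and Npas2 are among them (log2 1.05 to 1.26, adjusted p up to 0.0126).

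Beta-identity genes rose in 5 of 25 (7 up, 1 down alone), median log2 0.33 (total-count 0.72, endocrine 0.03), adjusted p = 0.00104; the factor genes Pdx1 and Nkx2-2, Glp1r and Ucn3 are among them (log2 0.66 to 1.10, adjusted p up to 0.0301). Ins1, Ins2, Mafa, Slc2a2, Dbp, Nr1d1 and Per2 did not pass (log2 -0.62 to 2.57, adjusted p at least 0.232), and Gcg and Cdkn1a were lower (log2 -0.81 to -0.72, adjusted p up to 0.0016). Liver genes took 0.204% of counts and intestinal genes 0.0388%, against 0.0196% and 0.00698% under vehicle. Prap1, Adh6a, Clca4b, Clec2h and Slc13a1 of gut or kidney and Cyp4a12a and Elovl3 of liver or skin glands had 0 counts under vehicle (at least 288-fold each). Sis and Mep1b had ratios of 3480 (95% interval 1190 to 16900) and 490 (95% interval 167 to 2380), and Akp3 was at 10.38, adjusted p = 4.12e-05. The stomach genes Gkn2, Gkn1, Tff1, Muc5ac, Psca and Cldn18 had 0 counts at 4 wk (at least 361-fold each), and Dpcr1, Ctse, Reg3a and Cr2 fell (log2 -7.79 to -7.31, adjusted p up to 0.000844). Calls of Psca, Cldn18, Usp2, Ccl3, Nkx2-2, Pdx1, Ucn3 and Npas2 ended without A or B of either group (adjusted p 0.0502 to 0.178).

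Knockout islets at 4 wk after STZ, against knockout vehicle at 24 h, had higher macrophage, interferon and antioxidant genes and lower beta-cell genes. In all, 6244 genes passed, 4199 higher and 2045 lower. Under total-count scaling 3667 were higher and 4409 lower (median gene -0.22), and under pan-endocrine scaling 10009 and 44 (median 0.81). Macrophage genes rose in 26 of 28 (28 up, 0 down alone), median log2 2.39, adjusted p = 1.58e-13; Lgals3, Lyz2, Ctss and H2-Aa led (log2 2.38 to 6.62, adjusted p up to 6.99e-07). Interferon genes rose in 28 and fell in 1 of 36 (29 up, 1 down alone), median log2 1.19 (endocrine 1.99), adjusted p = 2.47e-08, led by Gbp3, Gbp2, Oasl2 and Irf8 (log2 1.77 to 3.67, adjusted p up to 2.35e-05). Antioxidant genes under NRF2 rose in 23 of 30 (24 up, 1 down alone), adjusted p = 2.47e-08. They include the catalase gene Cat and the glutathione transferase genes Gsta4 and Gsta3 (log2 4.72 to 6.78, adjusted p up to 1.64e-07) and Gsta1 (at least 18300-fold), which liver and gut also make. Beside these, acinar genes rose in 26 and fell in 2 of 30 (27 up, 2 down alone), median log2 1.37 (endocrine 2.14), adjusted p = 2.47e-08, from 12.5% to 25.1% of counts, and liver genes went from 0.00476% to 0.539%.

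Of 25 beta-identity genes, 19 fell (0 up, 20 down alone), median log2 -0.85 (endocrine -0.05), adjusted p = 1.33e-10, and their share went from 13.6% to 6.72% ± 2.27 of counts. Trpm5, Glp1r, Slc30a8, Ucn3, Slc2a2 and Gcg fell (log2 -1.60 to -0.42, adjusted p up to 0.026; endocrine 0 to 0.38 for Slc2a2 and Gcg). Ins1, Ins2 and Mafa did not pass (log2 -0.85 to -0.41, adjusted p at least 0.141), although Ins2 had adjusted p = 0.0215 without knockout STZ 4 wk B. Core clock genes fell in 4 of 11 (0 up, 4 down alone), median log2 -0.42 (total-count -0.67, endocrine 0.38, adjusted p = 0.426), adjusted p = 0.0298, and adjusted p = 0.0822 with an estimated correlation; the list had adjusted p = 0.0584 without knockout vehicle A and 0.0523 without knockout STZ 4 wk A. Arntl, Nfil3, Cry1 and Per2 were lower (log2 -0.82 to -0.39, adjusted p up to 0.0363; endocrine 0.07 to 0.40 for Arntl, Cry1 and Per2), and Dbp, Nr1d1, Cdkn1a and Prss2 were higher (log2 0.97 to 2.52, adjusted p up to 0.00124). Intestinal genes went from 0.0111% to 1.38% of counts: Lct, Clca4b, Cdh17, Alpi, Cyp3a25, Mep1b, Clec2h, Clca1, Adh6a and Ces2c had 0 counts under vehicle (at least 21700-fold each). The largest losses besides Trpm5 were Atp6v0c, the mesothelial gene Msln, Adam32, Diras2, Peg10, Runx1t1, Stxbp5l, Hspa1a and Cdh7 (log2 -6.35 to -1.57, adjusted p up to 0.0349). Calls of Runx1t1, Hspa1a, Cry1, Slc2a2 and Per2 ended without A or B of either group (adjusted p 0.0583 to 0.211).

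Between 24 h and 4 wk after STZ, control islets lost matrix, immediate early and cell-cycle transcripts, and acinar, macrophage, inflammatory and liver transcripts fell with them. In all, 956 genes passed (1989 with the GC offset), 221 higher and 735 lower, and pan-endocrine scaling put the median gene at -0.14. Without A or B of either group, between 499 and 614 passed. Stellate-cell and fibroblast genes fell in 13 of 24 (0 up, 18 down alone), median log2 -1.34, adjusted p = 2.21e-16, led by Col3a1, Bgn, Pdgfra and Vim (log2 -1.77 to -0.95, adjusted p up to 0.000573). Immediate early genes fell in 11 of 22 (1 up, 16 down alone), median log2 -1.22, adjusted p = 2.54e-13, led by Fosb, Fos, Zfp36 and Jun (log2 -2.78 to -1.28, adjusted p up to 0.000393). Proliferation genes fell in 5 of 32 (0 up, 16 down alone), median log2 -0.69, adjusted p = 7.99e-11, led by Cenpe, Cdk1, Cenpf and Bub1b (log2 -1.68 to -0.99, adjusted p up to 0.0231). Beside these, acinar genes fell in 8 of 30 (0 up, 13 down alone), median log2 -0.36, adjusted p = 8.02e-11, macrophage genes in 10 of 28 (1 up, 10 down alone), median log2 -0.56, adjusted p = 1.32e-05, NF-kB targets in 11 of 33 (adjusted p = 2.14e-07) and liver genes in 20 of 20, with median log2 -1.78, adjusted p = 9.2e-40, from 0.658% to 0.204% of counts. Core clock genes rose in 3 of 11 (4 up, 0 down alone), median log2 0.23 (endocrine 0.08), adjusted p = 0.00231; these were Arntl, Cry1 and Npas2 (log2 0.64 to 0.90, adjusted p up to 0.0494). E-box outputs fell in 3 of 14 (0 up, 5 down alone), median log2 -0.45, adjusted p = 5.76e-05; these were Bhlhe40, Tef and Ciart (log2 -1.12 to -0.49, adjusted p up to 0.0417). No beta-identity gene passed, though the list as a whole leaned higher, with median log2 0.16 (endocrine 0, adjusted p = 0.0601), adjusted p = 0.0119 and adjusted p = 0.0757 without control STZ 4 wk B. Ins1, Ins2, Mafa, Slc2a2, Gcg, Cdkn1a, Dbp, Nr1d1, Per2 and Prss2 did not pass (log2 -1 to 0.88, adjusted p at least 0.0665). Gut genes rose, with Adh6a at least 982-fold higher and Sis, Cyp2c66, S100g and Akp3 following (log2 7.07 to 11.37, adjusted p up to 0.000174). The acute-phase liver genes Saa2, Saa1 and Orm2 and the lymphatic genes Ccl21b and Mmrn1 fell (log2 -7.20 to -4.23, adjusted p up to 0.0092). Calls of Mmrn1, Cdk1, Cenpf, Bub1b, Cry1, Npas2, Tef and Ciart ended without A or B of either group (adjusted p 0.0506 to 0.266).

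Over the same interval, inflammatory and acinar genes of knockout islets came down. In all, 6211 genes passed, 3512 higher and 2699 lower. Under total-count scaling 5285 were higher and 2074 lower (median gene 0.33), and under pan-endocrine scaling 586 and 11572 (median -1.07), and 3922 genes passed without knockout STZ 24 h B. Acinar genes fell in 19 of 30 (0 up, 24 down alone), median log2 -0.97 (endocrine -2.15), adjusted p = 1.82e-11, led by Prss3, Try5, Reg2, Try10 and Prss2 (log2 -5.57 to -1, adjusted p up to 0.000119). Macrophage genes fell in 23 and rose in 1 of 28 (1 up, 25 down alone), median log2 -1.64 (endocrine -2.82), adjusted p = 4.69e-11, led by Lyz2, Cd163, Adgre1 and Mrc1 (log2 -4.09 to -2.31, adjusted p up to 6.84e-05). NF-kB targets fell in 21 of 33 (0 up, 22 down alone), adjusted p = 1.41e-09, led by Vcam1, Lcn2, Saa3 and Icam1 (log2 -7.81 to -2.66, adjusted p up to 8.19e-05). Liver genes fell with them in 18 of 20 (adjusted p = 1.23e-14) and lymphoid-tissue genes in 19 of 20 (adjusted p = 5.86e-17), and intestinal genes rose in 20 of 20 (adjusted p = 9.08e-16). Beta-identity genes rose in 21 of 25 (22 up, 0 down alone), median log2 1.09 (endocrine -0.07), adjusted p = 4.23e-08. Iapp, Slc2a2, G6pc2, Trpm5, Ins1, Ins2 and Gcg were higher (log2 1.22 to 1.79, adjusted p up to 0.0343), and Mafa was at 1.97, adjusted p = 0.226. Core clock genes rose in 6 of 11 (6 up, 1 down alone), median log2 0.54 (endocrine -0.64, adjusted p = 0.504), adjusted p = 0.0264, and adjusted p = 0.0882 with an estimated correlation. Npas2, Cry1, Nfil3, Arntl and Per2 were higher (log2 0.32 to 1.68, adjusted p up to 0.0497; endocrine -0.84 to -0.31 for Arntl, Cry1, Nfil3 and Per2), and Dbp and Nr1d1 did not pass (log2 0.26 to 0.39, adjusted p at least 0.466; endocrine -0.93 for Dbp). Cdkn1a was at -0.99, adjusted p = 0.000104. Defa23, Defa17 and Defa3 had 0 counts at 24 h (at least 1280-fold each), and Defa24 and Enpp7 rose (log2 9.29 to 11.11, adjusted p up to 0.00208). Tff1, Retnla, Duoxa2 and Kel had 0 counts at 4 wk (at least 323-fold each), and the macrophage lectin gene Chil3 was at -8.40, adjusted p = 0.000634. Calls of Arntl, Nfil3, Ins1, Ins2 and Per2 ended without A or B of either group (adjusted p 0.0538 to 0.22).

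The interaction tests whether the STZ effect differs by genotype; a higher effect is a log2 change that lies higher in knockout, whatever its size. At 24 h the effect was higher in knockout for 3676 genes and lower for 2882, with 2436 higher and 7708 lower under total-count scaling (median gene -0.79) and 13486 higher and 66 lower under pan-endocrine scaling (median 2.09). All 30 acinar genes had a higher effect (30 up, 0 down alone), median log2 3.16 (endocrine 5.27), adjusted p = 3.1e-19, with Try5, Rnase1, Pnlip and Prss2 as examples (log2 3.03 to 3.96, adjusted p up to 1.05e-06). Macrophage genes had a higher effect in 26 of 28 (28 up, 0 down alone), median log2 3.34 (endocrine 5.45), adjusted p = 9.86e-15, led by Lyz2, H2-Aa, Ctss and Lgals3 (log2 3.10 to 4.68, adjusted p up to 2.22e-06). Beta-identity genes had a lower effect in 22 of 25 (0 up, 23 down alone), median log2 -2.35 (endocrine -0.24), adjusted p = 2.32e-14; Trpm5, Glp1r, Iapp, Slc30a8, Slc2a2, Ins1 and Ins2 are examples (log2 -2.74 to -2.35, adjusted p up to 0.00575). Core clock genes had a lower effect in 5 of 11 (0 up, 5 down alone), median log2 -1.18 (total-count -1.97, endocrine 0.93, adjusted p = 0.269), adjusted p = 0.00215, among them Arntl, Nfil3 and Npas2 (log2 -1.99 to -1.40, adjusted p up to 0.000665; endocrine 0.12 to 0.70 for all). Cdkn1a and Nr1d1 had higher effects (log2 2.02 to 2.86, adjusted p up to 0.018), Per2 and Gcg lower ones (log2 -1.51 to -1.07, adjusted p up to 0.00118; endocrine 0.59 to 1.04 for Gcg and Per2), and Dbp and Mafa did not pass (log2 -4.35 to 1.05, adjusted p at least 0.0504). The stomach genes Gkn2 and Gkn1 and the lymphoid genes Glycam1, Cr2 and H2-Eb2 head the higher effects (adjusted p up to 0.001), and Cox6a2, Esr1, Cntnap2, Tcf24 and Fam19a1 the lower ones (log2 -4.60 to -3.67, adjusted p up to 0.000211). Without control STZ 24 h A, control vehicle A, knockout STZ 24 h B and knockout vehicle B in turn the call of Nr1d1 ended (adjusted p 0.0573 to 0.0664), and Mafa had adjusted p = 0.0479 without knockout vehicle B. With letters paired Mafa and Dbp passed (adjusted p = 0.00101 for Mafa and 0.000502 for Dbp).

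At 4 wk, where treatment and time change together, the effect was higher in knockout for 3258 genes and lower for 1280 (7675 in all with letters paired, 6985 with the GC offset), with 2371 higher and 5832 lower under total-count scaling (median gene -0.62) and 9616 higher and 61 lower under pan-endocrine scaling (median 1.09). Acinar genes had a higher effect in 29 of 30 (30 up, 0 down alone), median log2 2.52, adjusted p = 5.07e-19, with Zg16, Pnlip, Pnliprp2 and Prss2 as examples (log2 2.54 to 2.82, adjusted p up to 3.84e-06). Macrophage genes did so in 26 of 28 (26 up, 0 down alone), median log2 2.17 (endocrine 3.26), adjusted p = 5.51e-12, led by Lgals3, Lyz2, Ctss and H2-Aa (log2 2.14 to 6.58, adjusted p up to 1.4e-05). E-box outputs had a higher effect in 11 and a lower one in 1 of 14 (11 up, 2 down alone), median log2 1.36 (total-count 0.73, endocrine 2.45), adjusted p = 0.000361. Bhlhe40, Tef, Usp2, Ciart, Dbp and Nr1d1 were higher (log2 1.03 to 3.05, adjusted p up to 0.00782). Core clock genes had a lower effect in 5 of 11 (0 up, 5 down alone), median log2 -0.96 (total-count -1.58, endocrine 0.15), adjusted p = 0.00121; Arntl, Nfil3, Cry1 and the E-box gene Per2 were lower (log2 -1.97 to -0.55, adjusted p up to 0.0423; endocrine 0.12 to 0.54 for Cry1 and Per2). Beta-identity genes had a lower effect in 19 of 25 (0 up, 19 down alone), median log2 -1.21 (total-count -1.84, endocrine -0.11), adjusted p = 1.87e-12, among them Glp1r, Trpm5, Ucn3, Foxa2 and Slc2a2 (log2 -2.15 to -0.62, adjusted p up to 0.0262; endocrine 0.06 to 0.47 for Foxa2 and Slc2a2). Ins1, Ins2, Mafa and Gcg did not pass (log2 -3.26 to 0.02, adjusted p at least 0.122; total-count -0.61 for Gcg), although without knockout STZ 4 wk B adjusted p was 0.0407, 0.018 and 0.0265 for the first 3. Cdkn1a was at 1.69, adjusted p = 3.01e-05. The gut genes Clca1, Gcnt3, Lypd8 and Clca4a and Gsta1 head the higher effects (adjusted p up to 0.0029), and Atp6v0c, Pcdha12, Pde10a, Diras2 and Cox6a2 the lower ones (log2 -6.80 to -2.53, adjusted p up to 0.0357). Calls of Clca4a, Pcdha12, Pde10a, Slc2a2 and Per2 ended without A or B of any group (adjusted p 0.0501 to 1). With letters paired Ins1, Ins2 and Mafa passed and Pde10a did not (adjusted p = 0.00255 for Ins1, 0.000385 for Ins2, 0.00311 for Mafa and 0.0689 for Pde10a).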

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

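The tests of beta against alpha genes and the values under pan-endocrine scaling were chosen after the result was seen. The tests of other splits and of the spread of liver genes were set out before their results, although the tissue lists themselves were made after seeing the data; that of Esr1 was too, but the exons it counts were chosen after their values were seen. Groups of 2 are too small for a test of outlying samples.

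The effect of STZ differed between genotypes, by a test of the interaction, for 6558 genes and 19 lists at 24 h and for 4538 genes and 20 lists at 4 wk. At 24 h the log2 differences were positive for Try5 3.96, Rnase1 3.25, Pnlip 3.03, Lyz2 4.36, H2-Aa 3.52, Ctss 3.10, Lgals3 4.68, Cdkn1a 2.86, Nr1d1 2.02 and Prss2 3.25. They were negative for Arntl -1.40, Cox6a2 -4.60, Esr1 -3.81, Cntnap2 -3.76, Tcf24 -3.71, Fam19a1 -3.67, Trpm5 -2.74, Glp1r -2.40, Iapp -2.48, Slc30a8 -2.37, Nfil3 -1.42, Npas2 -1.99, Ins1 -2.35, Ins2 -2.71, Slc2a2 -2.42, Gcg -1.51 and Per2 -1.07, of which Arntl, Nfil3, Npas2, Gcg and Per2 turned positive under pan-endocrine scaling. Fitted values for genes absent from a group depend on the prior count: Glycam1 23.42, Gkn2 23.31, Gkn1 23.27, Cr2 22.06 and H2-Eb2 20.38. At 4 wk they were positive for Zg16 2.82, Pnlip 2.63, Pnliprp2 2.73, Lgals3 6.58, Lyz2 2.77, Ctss 2.14, H2-Aa 2.29, Bhlhe40 2.24, Tef 1.03, Usp2 3.05, Ciart 2.47, Cdkn1a 1.69, Dbp 2.31, Nr1d1 2.59 and Prss2 2.54. Negative ones were Arntl -1.97, Atp6v0c -6.80, Pcdha12 -4.50, Pde10a -2.84, Diras2 -2.74, Cox6a2 -2.53, Glp1r -1.89, Trpm5 -1.39, Ucn3 -2.15, Foxa2 -1.03, Nfil3 -1.34, Cry1 -0.97, Slc2a2 -0.62 and Per2 -0.55, of which Foxa2, Cry1, Slc2a2 and Per2 turned positive under pan-endocrine scaling. The genes absent from a group had fitted values of Clca1 19.84, Gcnt3 16.44, Lypd8 16.43, Clca4a 16.18 and Gsta1 16.10.

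In the comparison of genotypes over 3 conditions, other splits of the libraries within conditions were counted. Of 100 splits drawn from 108, 3, the real one included, gave at least the real 5491 genes, so chance is excluded at the 0.05 level between libraries. It is not excluded between tissue preparations, which A and B of a group may share, because nearly all other splits part A from B. Of 31 drawn that part same-letter libraries in every condition, as the real one does, 2 gave as many, the real one included, so with letters paired that level is not reached. The highest other, 7809, swaps the genotype labels of the vehicle condition while keeping replicates together, and the highest that divides a group gave 5781. That points to a structure of the samples in which the vehicle difference runs against the STZ differences.

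The fall of beta-cell genes in knockout islets after STZ may reflect dilution of islet RNA by RNA of other tissues. Dilution would lower beta-selective and alpha-selective genes alike. At 24 h the beta-selective median lay -0.48 from the alpha-selective one (permutation p = 0.0372; bootstrap interval -1.06 to 0.06; 17 and 5 genes), while pan-endocrine genes had a median of -2.03: dilution stays open as the whole cause. At 4 wk the distance was -0.44 (permutation p = 0.00593; -1.32 to -0.03), which argues against dilution as the whole cause but rests on few alpha genes, with a pan-endocrine median of -0.78. Under pan-endocrine scaling beta-selective medians were -0.20 at 24 h (5 genes lower, 1 higher) and -0.07 at 4 wk (3 and 0). Against control, beta and alpha medians were -2.27 and -1.53 at 24 h, -1.12 and 0.02 at 4 wk. Beta-cell loss through genotype and STZ, which the design names, stays open as untested.

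Liver genes were higher in knockout than in control at 24 h after STZ in 20 of 20 cases, which may be liver RNA carried into the preparation. RNA from 1 source changes its genes by 1 factor. The SD of their log2 changes was 0.5 against a median of 1.27 for 10000 random lists matched on expression, which is percentile 0, as carried-over liver RNA needs. The 14, 19 and 3 intestinal, lymphoid and kidney genes tested had SDs of 2.53, 2.8 and 2.71 against random medians of 0.95, 1.26 and 0.71, at percentiles 98.2, 98.6 and 96.4, wider than 1 factor gives. Of these, 5, 18 and 1 lay under 1 CPM in control, where folds are uncertain, so their source stays open. No gene of the liver list is in another list. Alb, its most abundant, was at 10760 and 10130 CPM in knockout STZ 24 h A and B, 2853 and 2932 CPM in control STZ 24 h and 1.84 and 2.22 CPM in knockout vehicle. Why the amount differs by group was not tested, nor was any biological explanation.

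Exon coverage of Esr1, outside the gene counts, was far above control in knockout. Reads of the CreER transgene counted under Esr1 may explain this. Of the excess, 99.91% lay in the last 5 of 8 coding exons, from codon 258 on. Their mean coverage was 1409.5 in knockout and 1.23 in control, against 1.66 and 0.05 in the other coding exons. A rise of Esr1 itself was not tested apart from this.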

How the results depend on the processing

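Here vehicle, STZ 24 h and STZ 4 wk name the comparisons of knockout with control, the mean is that of all 3, and control or knockout with a time names STZ at that time against vehicle. Total-count and pan-endocrine scaling, the GC offset, the fragment scale and the pairing of letters within conditions were chosen after the data were seen; the other alternatives were planned. All 24 gene and list counts stayed within 1.5 times their value under DESeq2 size factors, no filter, the fragment scale and the replicate block. The gap between A and B ran both ways between groups of different conditions (correlations -0.74 to 0.52), so 1 block for all letters removes no shared effect. Pairing letters within conditions made 13 calls of named genes and ended 3, given with their comparisons, and changed no call of a described list. Adding the GC offset to that pairing (adjusted p in brackets) also made calls of Ins2 in vehicle (0.00425), Mafa in vehicle (0.0404), Arntl in STZ 24 h (0.0295) and Nr1d1 in STZ 4 wk (0.00546) and ended those of Pcdhac1 in STZ 24 h (0.0522) and Cyp2b9 in STZ 4 wk (0.0772). The acinar covariate was run for genes only, and fits of 4 libraries only for comparisons of 2 groups; genes without an adjusted p from DESeq2 have no value there.

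With the acinar score as a covariate the counts became 9292 in vehicle, 9618 in STZ 4 wk, 10159 in the mean, 9908 in control 24 h, 9545 in control 4 wk, 9581 in knockout 4 wk, 8587 in control 4 wk against 24 h and 9406 in the 4 wk interaction. Under total-count scaling they became 7205 in vehicle, 2634 in control 24 h, 4307 in control 4 wk, 10144 in the 24 h interaction and 8203 in the 4 wk interaction. With the GC offset they became 3128 in vehicle, 7568 in STZ 4 wk, 2515 in control 24 h, 2842 in control 4 wk, 1989 in control 4 wk against 24 h and 6985 in the 4 wk interaction. With the GC offset and replicate block they became 2902 in vehicle, 2279 in control 24 h, 2590 in control 4 wk and 1724 in control 4 wk against 24 h. Under pan-endocrine scaling they became 3423 in vehicle, 14554 in STZ 24 h, 9108 in STZ 4 wk, 12517 in the mean, 14792 in knockout 24 h, 10053 in knockout 4 wk, 12158 in knockout 4 wk against 24 h, 13552 in the 24 h interaction and 9677 in the 4 wk interaction. With only the 4 libraries compared they became 892 in vehicle, 11266 in STZ 24 h, 2147 in STZ 4 wk, 5423 in control 24 h, 907 in control 4 wk, 2882 in knockout 4 wk and 3957 in knockout 4 wk against 24 h. With the DESeq2 Wald test they became 2625 in vehicle, 2120 in control 24 h, 2406 in control 4 wk and 1759 in control 4 wk against 24 h. With letters paired within conditions they became 3533 in vehicle, 8184 in STZ 4 wk, 8619 in the mean and 7675 in the 4 wk interaction. With letters paired and the GC offset they became 4770 in vehicle, 9245 in STZ 4 wk, 9531 in the mean, 10336 in the 24 h interaction and 8696 in the 4 wk interaction. The cause was not tested. Apart from the scalings given with each comparison, the acinar covariate and the fits of 4 libraries, the share of higher genes moved by more than 10 points in vehicle from 20.4% to 31.2% (GC offset), 34.9% (letters paired) and 38% (letters, GC offset); in STZ 4 wk from 71.6% to 59.9% (GC offset), 60.3% (GC offset, block), 56.1% (letters paired) and 54.3% (letters, GC offset); in control 24 h from 71.5% to 56.9% (GC offset) and 59% (GC offset, block). It did so too in knockout 4 wk from 67.2% to 56.5% (GC offset), 56.6% (GC offset, block) and 77.5% (without knockout vehicle B); in control 4 wk against 24 h from 23.1% to 34.6% (GC offset) and 33.8% (Wald test); in the 4 wk interaction from 71.8% to 61.6% (GC offset), 57.3% (letters paired) and 56.1% (letters, GC offset). Leaving out 1 library gave 1070 to 1228 in vehicle, 770 to 854 in control 24 h, 941 to 1131 in control 4 wk, 499 to 614 in control 4 wk against 24 h and 3922 to 6468 in knockout 4 wk against 24 h. With an estimated correlation the number of lists past the threshold went from 17 to 9 in vehicle, from 21 to 12 in STZ 4 wk, from 19 to 12 in the mean, from 8 to 3 in control 24 h, from 15 to 5 in control 4 wk and from 18 to 9 in knockout 4 wk against 24 h. Pan-endocrine scaling took it from 8 to 5 in control 24 h. The other counts kept to within 1.5 times. Pan-endocrine scaling ended the calls of 5 described lists and the GC offset, with or without the block, that of 1, given with their comparisons. Scaled to library totals, exon 8 of Arntl lost its call.

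Of 532 values for named genes, 529 kept direction and side of the threshold under DESeq2 size factors, 529 without a filter, 529 on the fragment scale, 521 with the replicate block, 519 with the Wald test, 509 with the GC offset, 507 under total-count scaling, 439 under pan-endocrine scaling and 359 with the acinar covariate. In fits of only the 4 libraries compared 359 kept both, 11 calls were made and 41 ended: Hspa1a and Nkx2-2 in vehicle; Amd1 and Pcdhac1 in STZ 24 h; Arntl, Aak1, Mup15, Cacna1c, Chgb, Cacna1d, Rapgef4, Tef, Ins1, Slc2a2, Dbp, Per2 and Prss2 in STZ 4 wk; Bhlhe40, Nfkbia, Ccl3, Nkx2-2, Ucn3 and Npas2 in control 4 wk; Arntl, Runx1t1, Hspa1a, Nfil3, Cry1, Slc2a2, Gcg and Per2 in knockout 4 wk; Cenpf, Bub1b, Cry1, Npas2, Tef and Ciart in control 4 wk against 24 h; Arntl, Nfil3, Ins2 and Per2 in knockout 4 wk against 24 h. Leaving out 1 library ended 158 calls, made 9 and reversed 1. The acinar score varies between A and B by at most 0.25 against a span of 2.49 between groups, so the covariate nearly stands for the groups. Signs that turned where neither value passed (56 cases for genes, 0 for lists) are not counted as reversed. With the acinar covariate the reversed log2 values were Tcf24 -1.18, Scd2 -0.29, Hmgcs1 -1.83, Sqle -0.68, Egr1 0.19, Cry2 1.28, Ins1 6.73, Slc2a2 -1.79, Dbp 3.68 and Nr1d1 6 in vehicle; Amd1 0.19 and Per2 -1.04 in STZ 24 h; Mup15 0.18, Dbp -0.03 and Nr1d1 -1.17 in STZ 4 wk. Others were Mafa 0.88 in the mean; Cenpe -0.17 in control 24 h; Fam19a1 0.43, Cry1 0.67, Slc2a2 0.07, Dbp -4.52 and Nr1d1 -7.51 in knockout 24 h. These were joined by Jun 0.17, Cry2 0.01, Usp2 2.05, Slc2a2 -0.95, Dbp 2.57 and Nr1d1 5.09 in control 4 wk; Peg10 0.55, Stxbp5l 0.75, Cdh7 1.15, Cry1 0.48, Slc2a2 0.59, Dbp -1.14 and Nr1d1 -2.08 in knockout 4 wk; Ins1 1.47, Ins2 1.92 and Nr1d1 1.63 in control 4 wk against 24 h. The rest included Icam1 0.08 and Cry1 -0.19 in knockout 4 wk against 24 h; Tcf24 1.34, Fam19a1 1.61, Slc2a2 0.47, Dbp -6.97 and Nr1d1 -10.97 in the 24 h interaction; Cry1 1, Usp2 -3.07, Slc2a2 1.55, Dbp -3.71 and Nr1d1 -7.17 in the 4 wk interaction. Under pan-endocrine scaling the reversed log2 values were Arntl 1.46, Cacna1d 0.14, Chgb 0.05, Gcg 0.27, Dbp 1.32 and Nr1d1 1.43 in STZ 24 h; Cacna1c 0.03, Chgb 0.08, Cacna1d 0.19, Rapgef4 0.13 and Slc2a2 0.16 in STZ 4 wk; Cacna1d 0.07, Gcg 0.24, Dbp 0.35 and Prss2 0.46 in the mean. Others were Arntl 0.92, Nfil3 0.60, Cry1 0.67, Ins1 0.12 and Per2 1.03 in knockout 24 h; Arntl 0.07, Cry1 0.35, Slc2a2 0.38, Gcg 0 and Per2 0.40 in knockout 4 wk; Arntl -0.84, Cry1 -0.31, Nfil3 -0.64, Dbp -0.93 and Per2 -0.62 in knockout 4 wk against 24 h. These were joined by Arntl 0.70, Nfil3 0.69, Npas2 0.12, Gcg 0.59 and Per2 1.04 in the 24 h interaction; Foxa2 0.06, Cry1 0.12, Slc2a2 0.47 and Per2 0.54 in the 4 wk interaction. Under total-count scaling the reversed log2 values were Cdkn1a 0.44 in vehicle; Gcg -0.61 in the 4 wk interaction. Amd1 at 24 h after STZ ran from -10.70 without control STZ 24 h A to 0.16 without control STZ 24 h B, since its level rests on that library. Apart from Amd1 and the covariate's overlap with the groups, the cause was not tested. Depth limits folds against 0 counts, nominally bounded by 3 counts over the group.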

Other observations

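The genes below were picked after their values were seen, as were the tests of replicates A and B. Genes higher in knockout in all 3 conditions numbered 40, against 49.4 if the vehicle calls were independent of the 2514 genes higher in both STZ comparisons, so they are no excess. Genes lower in all 3 numbered 17 against 83.5. Among the higher ones are the clock genes Npas2, Cry1 and Nfil3, the retinoic acid gene Aldh1a3, which marks dedifferentiating beta cells, the interferon-inducible Ifi202b and Esr1, whose counts may be reads of the transgene. Their smallest log2 fold changes over the conditions were 1.51 for Npas2, 1.36 for Cry1, 0.40 for Nfil3, 1.17 for Aldh1a3 and 4.74 for Esr1; Ifi202b had 0 counts in 5 of 6 control libraries, so no value is given. Among the lower ones are Glul and Gad1 of glutamate metabolism, the fumarase gene Fh1, the kinase-like gene Trib1 and the neuronal genes Kcnf1 and Cntnap2, with smallest changes of -0.71 for Glul, -0.62 for Gad1, -0.53 for Fh1, -0.36 for Trib1, -1.56 for Kcnf1 and -0.52 for Cntnap2. Pan-endocrine scaling put the median gene at 1.72 at 24 h and 0.72 at 4 wk after STZ, so the direction of any smaller fall in that condition depends on the scaling, as for Glul, Fh1 and Trib1 at 24 h and Trib1 at 4 wk. Total-count scaling put it at 0.53 under vehicle, about the size of the falls of Fh1 and Cntnap2 there.

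The responses to STZ of both genotypes, which share no library, were compared across genes, which are not independent replicates. At 24 h Pearson's r was 0.4 and Spearman's rho 0.25; 869 genes rose in both, against 284 by chance (in brackets below), 58 fell in both (98), 267 fell in control and rose in knockout (113) and 50 did the reverse (247). At 4 wk r was 0.37 and rho 0.05; 636 rose in both (209), 41 fell in both (82), 473 fell in control and rose in knockout (168) and 135 did the reverse (102). The genotype differences at 24 h and 4 wk after STZ had r 0.6 and rho 0.68.

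Fat and kidney genes took 0.00183% and 0.00502% of control vehicle counts and at most 0.00769% and 0.022%, in knockout at 4 wk.

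A and B of a group may come from the same tissue preparation. The largest log2 gap between them in the share of liver, intestinal, lymphoid or stomach genes was 0.48, with a median of 0.09 over 24 gaps, against 2.8 between groups. The largest exceeds 0.28, the 5th percentile of gaps between groups, so the question stays open.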
